A study of Mus musculus with 6 samples.

How the data were processed

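Messenger RNA was measured in 6 libraries of mouse embryonic fibroblasts, 3 from K68R knock-in and 3 from WT embryos. Per the labels' protocols, RNA was extracted with Triazol and a column kit, had an RNA integrity number above 4, and was made into libraries with a stranded kit for poly(A) RNA. Per the submitters' processing notes, bcl2fastq, HISAT2 2.2.1, SAMtools and featureCounts 2.0.6 were used with build mm39. The authors deposited raw counts of read pairs per gene over its exons, not normalized, with 1 column per library. Per the file headers, featureCounts counted read pairs over exons of the NCBI RefSeq annotation of mm39 without a strand option and without counting multi-mapped reads. The libraries came from a stranded kit but were counted without strand, so reads of overlapping genes on opposite strands cannot be assigned to either, and genes with near-identical copies can lose reads. The same file gives the exonic length of each gene, which was used here. How reads were trimmed or filtered before alignment is not given in the sources used here.

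Samples were grouped by genotype from their titles. The labels call them biological replicates, and nothing says whether the cells of a library came from separate embryos, litters or cultures, so p-values then measure only the spread between these samples, which may be technical. Within a genotype, pairs of libraries differed by a chi-square of 1.89 to 2.32 per gene, above sampling noise, so all 6 were used as separate libraries. Between genotypes the same measure was 331 to 417. On the 500 most variable genes the first principal component separated the genotypes and held 98.5% of the variance.

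Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with default settings, library sizes were normalized by TMM, and genotypes were compared with the robust quasi-likelihood F test with no further term in the model. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. CPM values used TMM-normalized library sizes, and log2 CPM used a prior count of 2. Levels are means ± SD of 3 libraries. Library totals ran from 26200088 to 40691447, and a floor of 3 counts corresponded to 0.0728 to 0.116 CPM. The 95% interval of a ratio of counts was an exact binomial interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

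Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, for lists with 5 or more tested genes, with Benjamini-Hochberg adjustment over the 29 lists tested. The same test with a correlation estimated per list and fry, which asks whether the genes of a list move one way on balance, were run beside it. The sex linked genes, the C57BL/6 substrain genes and the neighbours of Sod2 were described gene by gene, and the erythroid and hepatic markers had too few tested genes. A single Sod2 comparison and ratios of 2 genes were tested by two-sided exact permutation over 20 assignments.

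The genes named in the text followed a rule. Sod2, Nnt, Xist and 4 Y-linked genes were always named. To these were added the 8 higher and 8 lower called genes with the largest fold change, at 5 CPM or more in the higher group, with no overlap of values and with an established symbol. The 3 genes with the smallest p and, for each list, up to 3 called members with the smallest p completed the rule. Any other gene is said to have been chosen after its values were seen. The test of the comparison, the list tests, the lists, the naming rule and all alternatives except those that concern length and GC content were chosen before the data were examined. List medians were also set against random lists drawn gene by gene from the genes nearest in exon length and GC content. This test was fixed beforehand for the extracellular matrix list alone, and its reading was changed after the result. The ratios of 2 genes and several tests of explanations were chosen after the results were seen.

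Because fold changes varied with exon length and GC content, 2 alternatives were added after seeing the data. In the first, a smooth surface over log2 exon length and GC content was fitted per library with mgcv 1.9.3 and entered as offsets in the edgeR model. In the second, only genes under 4000 exonic bases and under 50% GC were tested. GC content came from GENCODE M21 transcripts of build GRCm38, joined by symbol only, and no coordinates of that build were used. Of the 50763 symbols, 36310 matched directly and 616 through an older symbol, and 15682 of the genes tested (93.7%), and 94.8% of those called, had a value. The alternatives fixed beforehand were DESeq2 size factors, upper quartile normalization, no filter or a stricter one of 1 CPM, DESeq2 1.42.0, limma-voom, a replicate block, a test against 1.5-fold, an adjusted p under 0.01, leaving out genes of chromosomes X, Y and the mitochondrial genome, and leaving out each library.

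The fit was tested on simulated counts of this comparison for 15682 genes, with 50 genes changed at each fold size. Without a length and GC trend it recovered 64%, 90%, 100% and 98% of genes changed 1.2-fold, 1.5-fold, 2-fold and 4-fold, and called 12 unchanged genes. With a simulated trend, 12106 unchanged genes were called without offsets and 256 with them, when 66%, 82%, 98% and 96% of changed genes were recovered. The simulated trend followed length and GC content alone, and few genes were changed. The simulation therefore cannot show whether the offsets separate technical from biological change in these data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.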

Results

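Transcript levels were measured by RNA sequencing in mouse embryonic fibroblasts, the mesenchymal cells that grow out when the body of a midgestation embryo is dissociated and plated. The cells came from embryos on a C57BL/6 background and were cultured briefly before RNA was taken. The 2 genotypes were wild type (WT) and K68R, a CRISPR knock-in that puts an arginine in place of a lysine of SOD2 and so mimics the form that is not acetylated. SOD2, or MnSOD, is the manganese superoxide dismutase of the mitochondrial matrix, which turns superoxide into hydrogen peroxide. Each genotype had 3 libraries. The deposited counts of read pairs summed to 26200088, 31738219 and 31330555 in the K68R libraries and to 40691447, 30856781 and 32994101 in the WT libraries. A floor of 3 counts corresponded to between 0.0728 and 0.116 CPM (counts scaled to a common library size) per library.

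The comparison of K68R with WT asked how the transcriptome of embryonic fibroblasts differs in a knock-in line whose adult mice the study describes as having dilated cardiomyopathy. In the K68R cultures the interferon stimulated genes and the proliferation genes were lower, and the skeletal myogenic markers, the limb and craniofacial transcription factors and the genes linked to dilated cardiomyopathy were higher. Isg15, a ubiquitin-like modifier induced by interferon, was 26.8-fold lower, at 2.73 ± 0.279 CPM in K68R and 72.7 ± 1.65 CPM in WT (SD, n = 3). Ccnb1, the cyclin that drives entry into mitosis, was 3.50-fold lower, at 55.7 ± 3.13 against 195 ± 3.13 CPM (SD, n = 3). Myh3, the embryonic skeletal myosin heavy chain, was 49.9-fold higher, at 52.8 ± 1.78 against 1.04 ± 0.273 CPM (SD, n = 3). After adjustment for exon length and GC content, Isg15 was 17.8-fold lower, Ccnb1 2.68-fold lower and Myh3 22.5-fold higher. The plot of 16 genes per library shows these values beside others named in the text.

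**Figure D1:**
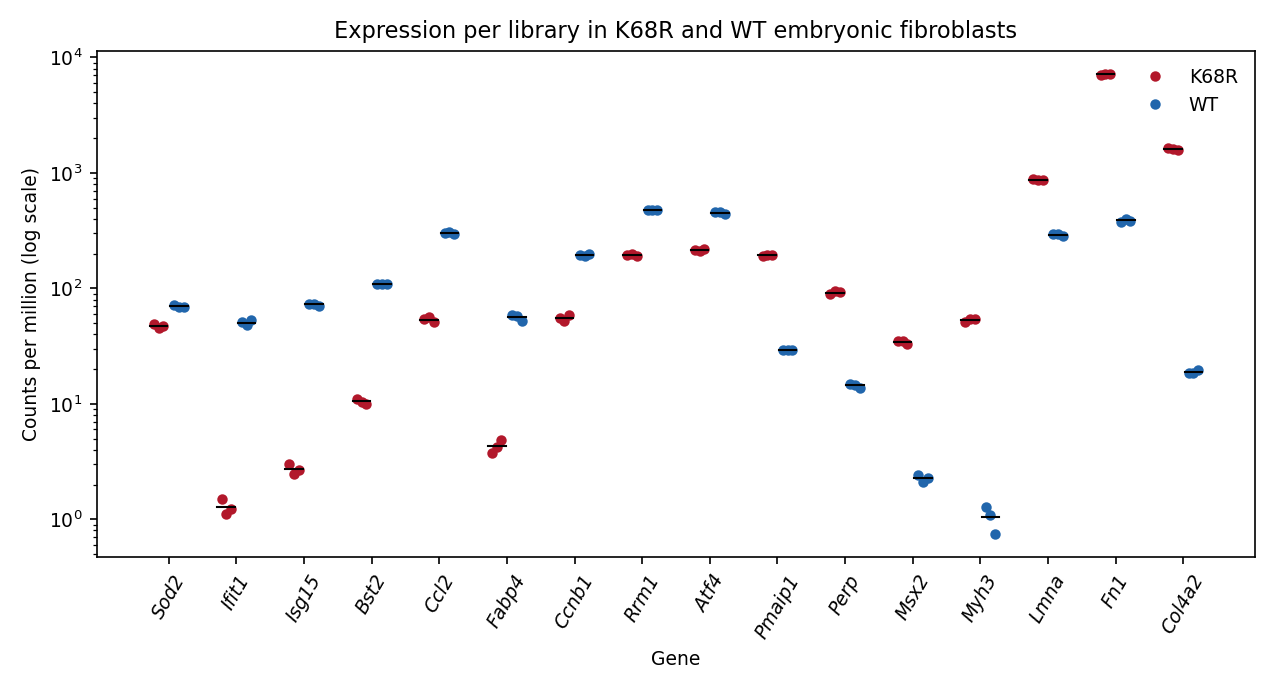
CPM on a log axis of 16 genes in the 3 K68R and 3 WT libraries; points are libraries and short lines are means of a genotype. Isg15 lies at 2.73 CPM in K68R and 72.7 CPM in WT on average, and Myh3 at 52.8 and 1.04 CPM.

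Sod2 itself (chromosome 17, 13226726 to 13237006, plus strand, build mm39) was expressed in every library. Its level was 48.9, 45.6 and 47.2 CPM in the K68R libraries and 71.8, 68.9 and 69.2 CPM in the WT libraries. The K68R mean of 47.2 ± 1.62 CPM was 1.49-fold lower than the WT mean of 70.0 ± 1.58 CPM (SD, n = 3), a log2 fold change of K68R over WT of -0.57 with a standard error of 0.0363 and an adjusted p = 2.96e-23 (edgeR, Benjamini-Hochberg). A two-sided exact permutation test of the 6 Sod2 values gave p = 0.1, the smallest that 3 against 3 libraries allow. The counts cover all exons of the gene and do not distinguish the knock-in codon. Against a bound of 1.5-fold instead of no change, the adjusted p for Sod2 was 0.692 (edgeR), and over all alternatives it ranged from 3.07e-59 to 0.692. After adjustment for exon length and GC content the log2 fold change was -0.22.

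Of 50763 genes in the table, 16730 were tested and 13613 (81.4%) differed between genotypes at an adjusted p under 0.05 (edgeR, Benjamini-Hochberg), with 6833 higher and 6780 lower in K68R. At least 4-fold changes were unequal in number, with 1683 genes higher and 278 lower, and with offsets for exon length and GC content 618 higher and 329 lower. In 13772 genes (82.3%) the 3 values of one genotype did not overlap those of the other, against 10% by chance. The spread between libraries of a genotype was small, with a common biological coefficient of variation of 2.19%, so that small changes passed the test. Libraries of a genotype may come from 1 pool of cells or RNA. The p-values may then measure technical spread only, and not the spread between embryos of a genotype. Against a 1.5-fold bound, 4365 genes were higher and 2490 lower.

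The largest increases, among genes at 5 CPM or more in the higher genotype, were, apart from Sts, in long transcripts rich in G and C. Apc2, a relative of the Wnt pathway scaffold Apc, rose from 0.0479 ± 0.0631 to 17.0 ± 1.24 CPM, and Col2a1, the main collagen of cartilage, from 0.588 ± 0.113 to 134 ± 4.42 CPM (SD, n = 3). Hspg2, the basement membrane proteoglycan perlecan, was 119-fold higher at 1885 ± 33.4 against 15.8 ± 0.390 CPM (SD, n = 3) and had the smallest adjusted p of the table, 1.02e-95 (edgeR). It was followed by Col4a2, a chain of basement membrane collagen (adjusted p = 2.64e-94), and Lrp1, a large endocytic receptor (adjusted p = 3.27e-94; edgeR). Plec, the cytoskeletal linker plectin, was 87.3-fold higher. Zfhx2, Lmtk3 and Sts had log2 fold changes of 7.06, 6.80 and 7.02. Other annotated genes share 16.9% of the exonic bases of Zfhx2 and 14.1% of those of Lmtk3, and Sts had no GC value, so these 3 are less certain.

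The largest decreases were in shorter transcripts. Adipoq, the adipocyte hormone adiponectin, had 1 count in the K68R libraries together and 1042 in the WT libraries, an 864-fold lower level with an exact binomial 95% interval from 155 to 34100 that covers counting error only. Hp, the haemoglobin scavenger haptoglobin, fell by 8.27 on the log2 scale, and Cfd, the adipocyte protease adipsin, by a log2 fold change of -6.73. Oasl1, an interferon stimulated relative of the oligoadenylate synthetases, changed by -6.22, Ifit1 by -5.30, Thbs4, an extracellular thrombospondin, by -5.23, and Krt14, a keratin of basal epithelium, by -5.18 (log2). Dpt, the matrix protein dermatopontin, changed by -5.64 (log2), with 21.8% of its exonic bases shared with another annotated gene.

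Fold changes depended on exon length and GC content across the transcriptome. Genes with at least 4000 exonic bases and at least 55% GC held 9.58 ± 0.0497% of K68R counts and 2.48 ± 0.00416% of WT counts (SD, n = 3). The 46 genes with at least 8000 bases and at least 60% GC had a median log2 fold change of 3.82, while the 361 genes with under 1000 bases and 45% to 50% GC had a median of -0.67. A smooth surface over length and GC content explained 39.8% of the variance of log2 fold changes over 15682 genes, a relation across genes, which are not independent replicates. With offsets that remove this surface in each library, 5255 genes were higher and 6629 lower (edgeR), and 1559 genes were called both ways with opposite signs. Of the 1505 genes at least 4-fold higher that had a GC value, 1056 stayed at least 2-fold higher with the offsets. So did Hspg2 (log2 fold change 3.30), Plec (2.80), Col4a2 (3.56), Lrp1 (2.85), Apc2 (4.96), Col2a1 (5.06), Zfhx2 (4.24) and Lmtk3 (3.42). These named genes were picked from the same data for a large fold change or a small p. Their values with offsets are therefore no separate support for a rise beyond length and GC content. All 264 genes at least 4-fold lower that had a GC value stayed at least 2-fold lower. That was close to fixed beforehand and does not test the decreases. No class of length and GC content had a median under -0.67 (log2), so the offsets raise such genes little. Because of this dependence on length and GC content, the adjusted log2 fold change is given for the median of each gene group that follows. It is given for only some of the named genes.

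**Figure D2:**
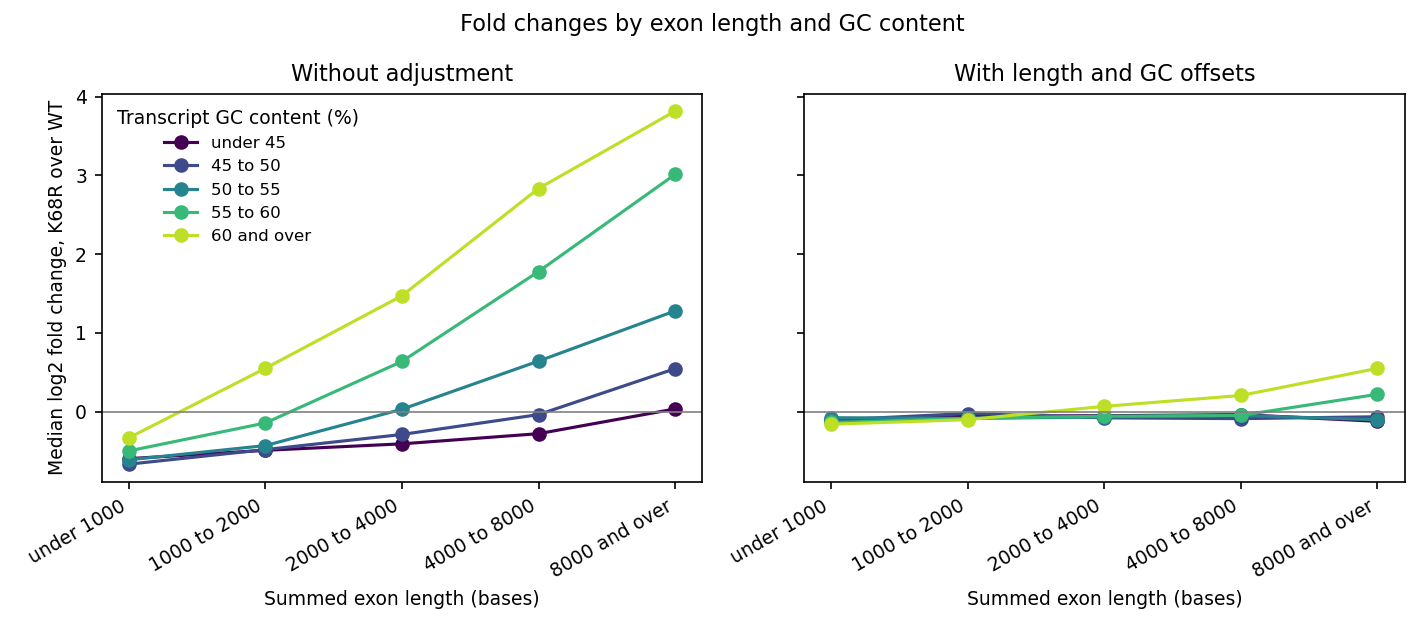
Median log2 fold change of K68R over WT (vertical axis) by class of exon length in bases (horizontal axis), with 1 line per class of GC content, unadjusted on the left and with length and GC offsets on the right. In the longest class of the highest GC content (46 genes) the median is 3.82 unadjusted and 0.55 with the offsets.

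Of 33 gene lists fixed in advance, 29 were given a list test, and 19 of them moved relative to the other genes (camera, Benjamini-Hochberg), 11 towards higher and 8 towards lower levels in K68R. With a correlation between genes estimated for each list in place of the preset value, 10 of the 19 kept their call, and the smallest adjusted p that this test gave was 0.0479. Among short genes of low GC content alone, 14 of the 19 called lists held enough genes for the test, and 8 of these lost their call. These short genes as a whole had a median of -0.43 (log2) when scaled with all genes and of 0 when scaled among themselves. The call was lost by antioxidant enzymes (camera, adjusted p = 0.566), TCA cycle (0.186), fatty acid oxidation (0.78) and integrated stress response genes (0.144), whose 14, 15, 9 and 9 short members had medians of -0.53, -0.53, -0.50 and -0.68 (log2) on the first scale and of -0.10, -0.10, -0.075 and -0.26 on the second. It was also lost by TGF-beta response (0.061) and dilated cardiomyopathy genes (0.0667), which rested there on 5 genes each, with medians of 0.17 and 0.31 on the first scale and of 0.60 and 0.73 on the second (quartiles 0.24 to 1.05 and 0.23 to 1.94). The 7 short members of the extracellular matrix list (0.0576) and the 6 of the cardiac transcription factors (0.76) pointed the opposite way, with medians of -1.34 and -0.55 (log2) on the second scale. Against 10000 random lists matched on exon length and GC content, the medians of 8 of the 19 called lists lay within the central 95%: antioxidant enzymes, nuclear genes of the respiratory chain, TCA cycle, extracellular matrix, calcium handling, cardiac transcription factors, immediate early and heat shock genes, and chondrogenic and osteogenic markers. In every list the counts of higher and lower members adjusted over the list alone equalled those over all genes tested.

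Interferon stimulated genes were lower in K68R. Of 37 tested members none was higher, 35 were lower and 2 were not called, and 33 were at least 2-fold lower, with a median 7.2-fold lower in K68R (camera, adjusted p = 1.53e-10; adjusted p = 0.0479 with an estimated correlation). Besides Isg15, Ifit1, which binds viral RNA, was at 1.29 ± 0.201 CPM against 50.5 ± 2.49 CPM, and Bst2, a membrane tether that holds budding virions, at 10.5 ± 0.532 against 109 ± 1.10 CPM (SD, n = 3). Another annotated gene overlaps 13% of the exonic bases of Isg15. The median log2 fold change was -2.85, and -2.82 with the length and GC offsets (camera, adjusted p = 1.99e-09). Among 30 inflammatory cytokine and NF-kB target genes, 8 were higher, 16 lower and 6 not called, and the list was not called (camera, adjusted p = 0.122), although with offsets it was called lower (adjusted p = 0.0381). Its median was -0.40, and -0.66 with offsets (log2). Within it the chemokines Ccl2, Ccl7 and Cxcl5 were 5.65-fold, 7.06-fold and 24.5-fold lower, and 3.66-fold, 4.89-fold and 18.8-fold lower with offsets. Macrophage markers, of which 6 were higher, 8 lower and 6 not called among 20, had a median log2 fold change of -0.01, which was 0.20 with offsets, and were not called (camera, adjusted p = 0.872). Lyz2, the lysozyme of macrophages, was at 82.7 ± 3.03 CPM in K68R and 100.4 ± 1.14 CPM in WT (SD, n = 3), and its log2 fold change of -0.28 became 0.19 with offsets. Laptm5, a lysosomal protein of leukocytes, was 3.15-fold higher and Fcgr1, an Fc receptor of macrophages, 3.01-fold lower, with 1.34 and -1.49 after adjustment (log2).

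Proliferation genes were lower. Of 40 members 4 were higher and 36 lower, 29 of them at least 2-fold, and the median was 2.39-fold lower (camera, adjusted p = 4.2e-09; adjusted p = 0.0479 with an estimated correlation). Rrm1, the large subunit of ribonucleotide reductase, was 2.45-fold lower at 194 ± 4.54 against 475 ± 3.36 CPM (SD, n = 3). Mki67, which encodes the nuclear proliferation antigen Ki-67 and has 10257 exonic bases, went the other way and was 4.40-fold higher, with an adjusted log2 fold change of 1.75. With length and GC offsets 1 member was higher and 38 lower, and the list median was -1.04 (log2). The list of replication dependent histones, whose main transcripts lack a poly(A) tail, went up in the same cells, with 22 higher, 4 lower and 11 not called among 37 (camera, adjusted p = 0.0166). That call was lost with an estimated correlation (adjusted p = 0.245 with an estimated correlation), and the median of 1.18 was 1.57 with the offsets (log2). H1f2, a linker histone of dividing cells, was 1.91-fold higher. The list as fixed also holds H1f0, a linker histone of non-dividing cells that is polyadenylated and not replication dependent, which was 1.54-fold lower, and without it 3 of 36 were lower and the median was 1.22 (log2). Targets of p53 and senescence genes were mostly higher, with 24 higher, 3 lower and 1 not called of 28 and a median 1.4-fold higher (camera, adjusted p = 1.74e-04; adjusted p = 0.0479 with an estimated correlation). Pmaip1, the pro-apoptotic protein Noxa, was 6.63-fold higher at 195 ± 2.63 against 29.4 ± 0.0760 CPM, and Perp, a p53 effector and desmosome component, 6.35-fold higher at 91.8 ± 2.84 against 14.4 ± 0.563 CPM (SD, n = 3). The death receptor Tnfrsf10b was 2.71-fold higher. The p53 list median was 0.48, and 0.49 with the offsets (log2).

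Antioxidant enzymes and nuclear genes of the respiratory chain, the setting in which SOD2 acts, were mostly lower, by small amounts. Of 35 antioxidant enzymes 6 were higher, 28 lower and 1 not called, with a median 1.30-fold lower (camera, adjusted p = 5.17e-04; adjusted p = 0.0479 with an estimated correlation). Txn1, the cytosolic thioredoxin, and Prdx4, a peroxiredoxin of the endoplasmic reticulum, were 2.09-fold and 2.32-fold lower, and 1.43-fold and 1.99-fold lower with offsets. Sesn2, a stress-induced sestrin, was 3.85-fold higher, with 1.13 (log2) after adjustment. With length and GC offsets the median was -0.11 (log2) and the list was no longer called (camera, adjusted p = 0.583). NRF2 targets were not called as a list (adjusted p = 0.218), with 11 higher, 17 lower and 5 not called of 33, a median of -0.27 (log2) and -0.17 with offsets. Its member Ugdh, which makes UDP-glucuronate, was 2.16-fold lower (1.68-fold with offsets) and Mgst1, a microsomal glutathione transferase, 2.55-fold lower (1.75-fold with offsets). Of 76 nuclear encoded genes of the respiratory chain 75 were lower and 1 higher, with a median 1.49-fold lower (camera, adjusted p = 2.85e-13), a call lost with an estimated correlation (adjusted p = 0.152 with an estimated correlation). Atp5f1a, the alpha subunit of ATP synthase, was at 689 ± 5.64 against 1136 ± 1.42 CPM (SD, n = 3). These are short transcripts, with a median of 922 exonic bases, and with offsets 13 were higher and 51 lower, with a median of -0.15 (log2; camera, adjusted p = 0.0102). Yet their unadjusted median of -0.575 lay at percentile 16.5 of 10000 random lists matched on length and GC content, of which the central 95% had medians from -0.653 to -0.354 (log2), and so within their range.

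The mitochondrially encoded genes of the respiratory chain were not called as a list (camera, adjusted p = 0.189), with 8 higher, 2 lower and 3 not called of 13. Their median was 0.33, and 0.63 with offsets (log2), when the list was called higher (adjusted p = 0.00522). ND5 and ND2, subunits of complex I, were 2.71-fold and 1.98-fold higher. Reads from the mitochondrial genome are uncertain here, since COX2, named with COX1 after their values were seen, averaged 206 counts in K68R and 194 in WT where COX1 averaged 165340 and 230890. Of 24 genes of the TCA cycle 3 were higher, 20 lower and 1 not called (camera, adjusted p = 5.17e-04; adjusted p = 0.173 with an estimated correlation), with a median of -0.49 and -0.14 with offsets (log2). Sdhd, a subunit of succinate dehydrogenase, was 1.63-fold lower (1.22-fold with offsets). Ogdh, of the oxoglutarate dehydrogenase complex, was 2.02-fold higher but at -0.15 (log2) with offsets. Pdha1, the pyruvate dehydrogenase subunit, was 1.60-fold lower (1.29-fold with offsets), with 20.9% of its exonic bases shared with another annotated gene. Fatty acid oxidation genes had 7 higher, 22 lower and 1 not called of 30 and a median of -0.43 (log2; camera, adjusted p = 0.0166; adjusted p = 0.196 with an estimated correlation), which was -0.19 with offsets, where the list was not called (adjusted p = 0.268). Ppard, a lipid-sensing nuclear receptor, was 6.57-fold higher (log2 fold change with offsets 2.56). Cpt1a, the carnitine transferase that admits fatty acids to mitochondria, was 1.77-fold higher (with offsets 0.40). Pparg, which is also among the adipogenic markers, was 4.15-fold lower (with offsets -2.04). Glycolysis and HIF target genes went both ways, with 14 higher, 15 lower and 7 not called of 36 (camera, adjusted p = 0.965). Their median was -0.01 and their mean 0.18 (log2), of opposite sign, and the median with offsets was -0.05. Ldha, lactate dehydrogenase A, was 1.55-fold lower, and Hk1, a hexokinase, was 2.98-fold higher but at -0.12 (log2) with offsets.

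Genes of the integrated stress response and mitochondrial proteostasis were lower, with 5 higher, 23 lower and 3 not called of 31 and a median 1.39-fold lower (camera, adjusted p = 0.00119; adjusted p = 0.0496 with an estimated correlation). Atf4, the transcription factor at the centre of that response, was 2.10-fold lower at 215 ± 5.19 against 453 ± 9.08 CPM (SD, n = 3), and Psat1, an enzyme of serine synthesis under its control, 2.40-fold lower. The list median was -0.48, and -0.40 with offsets (log2; camera, adjusted p = 0.00299). Immediate early and heat shock genes were higher, with 21 higher, 9 lower and 3 not called of 33 (camera, adjusted p = 0.0176; adjusted p = 0.104 with an estimated correlation). Their median was 0.62, and 0.32 with offsets (log2). Jun, a subunit of the transcription factor AP-1, was 2.99-fold higher, with 0.96 after adjustment (log2), whereas Jund, another subunit, was 2.84-fold higher and at -0.87 (log2) after adjustment. Cholesterol synthesis genes and other SREBP targets were not called (camera, adjusted p = 0.134), with 9 higher, 21 lower and 1 not called of 31. Their median of -0.24 and mean of 0.13 (log2) had opposite signs, and the median with offsets was -0.23. Fasn, the fatty acid synthase, was 23.5-fold higher (log2 fold change with offsets 1.56) and Srebf2, the regulator of cholesterol synthesis, 4.22-fold higher (with offsets -0.065).

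Extracellular matrix genes, many of them long and rich in G and C, split in direction. Of 55 members 33 were higher and 22 lower, with a median 1.58-fold higher (camera, adjusted p = 0.0393), a call lost with an estimated correlation (adjusted p = 0.242 with an estimated correlation) and without WT replicate 2 (adjusted p = 0.0505). Fn1, fibronectin, was 18.5-fold higher at 7154 ± 65.9 against 387 ± 10.05 CPM, Col4a2 was at 1605 ± 22.2 against 18.8 ± 0.708 CPM, and Col5a1, a fibrillar collagen chain, was at 1037 ± 4.997 against 24.1 ± 0.626 CPM (SD, n = 3). With length and GC offsets 27 members were higher and 23 lower and the list median was 0.08 (log2; camera, adjusted p = 0.243), while Fn1 stayed at 2.71, Col4a2 at 3.56 and Col5a1 at 2.48 (log2). The TGF-beta response and contractile genes of myofibroblasts were higher, with 29 higher, 5 lower and 5 not called of 39 and a median 1.54-fold higher (camera, adjusted p = 1.74e-04; adjusted p = 0.0479 with an estimated correlation). The non-muscle myosins Myh9 and Myh10 were 24.8-fold and 5.44-fold higher, with 2.13 and 1.31 after adjustment (log2), whereas the latent TGF-beta binding protein Ltbp2 was 6.42-fold higher and at -0.38 (log2) after adjustment. The median of this list was 0.25 (log2) with offsets (camera, adjusted p = 0.00111). Chondrogenic and osteogenic markers had 12 higher, none lower and 4 not called of 16, with a median of 0.97 and 0.27 with offsets (log2; camera, adjusted p = 0.0166; adjusted p = 0.113 with an estimated correlation). Sox9, the master regulator of cartilage, was 3.03-fold higher, with 1.49 (log2) after adjustment.

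Genes in which variants cause dilated cardiomyopathy were higher in the K68R cultures. Of 51 tested members 37 were higher, 11 lower and 3 not called, 28 were at least 2-fold higher, and the median was 2.46-fold higher (camera, adjusted p = 9.55e-04; adjusted p = 0.0479 with an estimated correlation). Flnc, the muscle actin crosslinker filamin C, was at 977 ± 10.6 against 21.8 ± 0.913 CPM, and Lmna, which encodes the nuclear lamins A and C, at 873 ± 10.2 against 291 ± 4.97 CPM (SD, n = 3). With length and GC offsets the list median was 0.99, Flnc was at 2.40, Lmna at 1.12 and the junction protein Jup at 1.16 (log2). Skeletal myogenic markers moved with this group, with 22 higher, none lower and 1 not called of 23 and a median 4.31-fold higher (camera, adjusted p = 1.06e-05; adjusted p = 0.0479 with an estimated correlation). The counts are of whole cultures and do not show whether both rises lie in fibroblasts or in other cells. Besides Myh3, the thin filament ruler Neb was 18.3-fold higher, with 3.37 (log2) after adjustment, and Acta1, the skeletal muscle actin, 2.04-fold higher at 62.2 ± 0.972 against 30.6 ± 1.03 CPM (SD, n = 3). Their list median was 2.11, and 2.44 with offsets (log2; camera, adjusted p = 1.08e-07). Calcium handling genes had 26 higher, 4 lower and 4 not called of 34 (camera, adjusted p = 5.17e-04; adjusted p = 0.0921 with an estimated correlation), with a median of 0.70 and 0.29 with offsets (log2). Jph2, a junctophilin that ties the sarcoplasmic reticulum to the cell membrane, was 25.1-fold higher, with 2.13 (log2) after adjustment, and the calcium channel subunit Cacnb3 was 3.79-fold higher and at -0.48 (log2) after adjustment.

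Transcription factors of cardiac mesoderm had 21 higher, 4 lower and 4 not called of 29 (camera, adjusted p = 0.00119; adjusted p = 0.0496 with an estimated correlation), with a median of 0.74 and 0.17 with offsets (log2; camera, adjusted p = 0.0369). Foxc1 and Foxc2, forkhead factors of heart and paraxial mesoderm, were 16.8-fold and 12.9-fold higher, with 3.01 and 2.30 after adjustment, and Tbx2, a T-box factor of the heart, 16.3-fold higher, with 1.79 after adjustment (log2). Transcription factors of limb and craniofacial mesenchyme were higher as a group, with 30 higher, 4 lower and 3 not called of 37 and a median 3.72-fold higher (camera, adjusted p = 3.24e-05; adjusted p = 0.0479 with an estimated correlation). Msx2, a homeobox factor of skull and limb buds, was 15.2-fold higher at 34.6 ± 1.25 against 2.26 ± 0.145 CPM, Alx4, an aristaless-like factor of the same tissues, 12.6-fold higher, with 2.50 (log2) after adjustment, and Twist2, a mesenchymal basic helix-loop-helix factor, 2.90-fold lower at 59.7 ± 0.287 against 173 ± 4.47 CPM (SD, n = 3). Pax7, also in the skeletal list and named after its values were seen, had no counts in WT, and setting it to a floor of 3 counts over the group left both list medians at 1.90 and 2.11 (log2). The limb list median was 1.90, and 1.26 with offsets (log2; camera, adjusted p = 2.16e-05).

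Adipogenic markers were lower, with 2 higher, 11 lower and 1 not called of 14 and a median 3.29-fold lower (camera, adjusted p = 0.00468), a call lost with an estimated correlation (adjusted p = 0.196 with an estimated correlation). Fabp4, the fatty acid binding protein of adipocytes, was at 4.28 ± 0.554 against 56.4 ± 3.47 CPM, Pparg, the nuclear receptor that directs adipogenesis, at 6.55 ± 0.482 against 27.0 ± 2.01 CPM, and Lpl, lipoprotein lipase, at 50.7 ± 2.32 against 132 ± 4.49 CPM (SD, n = 3). Dlk1, a preadipocyte protein that restrains adipogenesis, was also lower, by 2.40-fold, with -2.03 (log2) after adjustment. Plin1 and Pck1, named after their values were seen, had no counts in K68R, and with both set to a floor of 3 counts over the group the list median was again -1.72 (log2). The list median was -1.72, and -2.03 with offsets (log2; camera, adjusted p = 8.23e-04). The plot of list medians sets the unadjusted and the adjusted values of the 29 lists side by side.

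**Figure D3:**
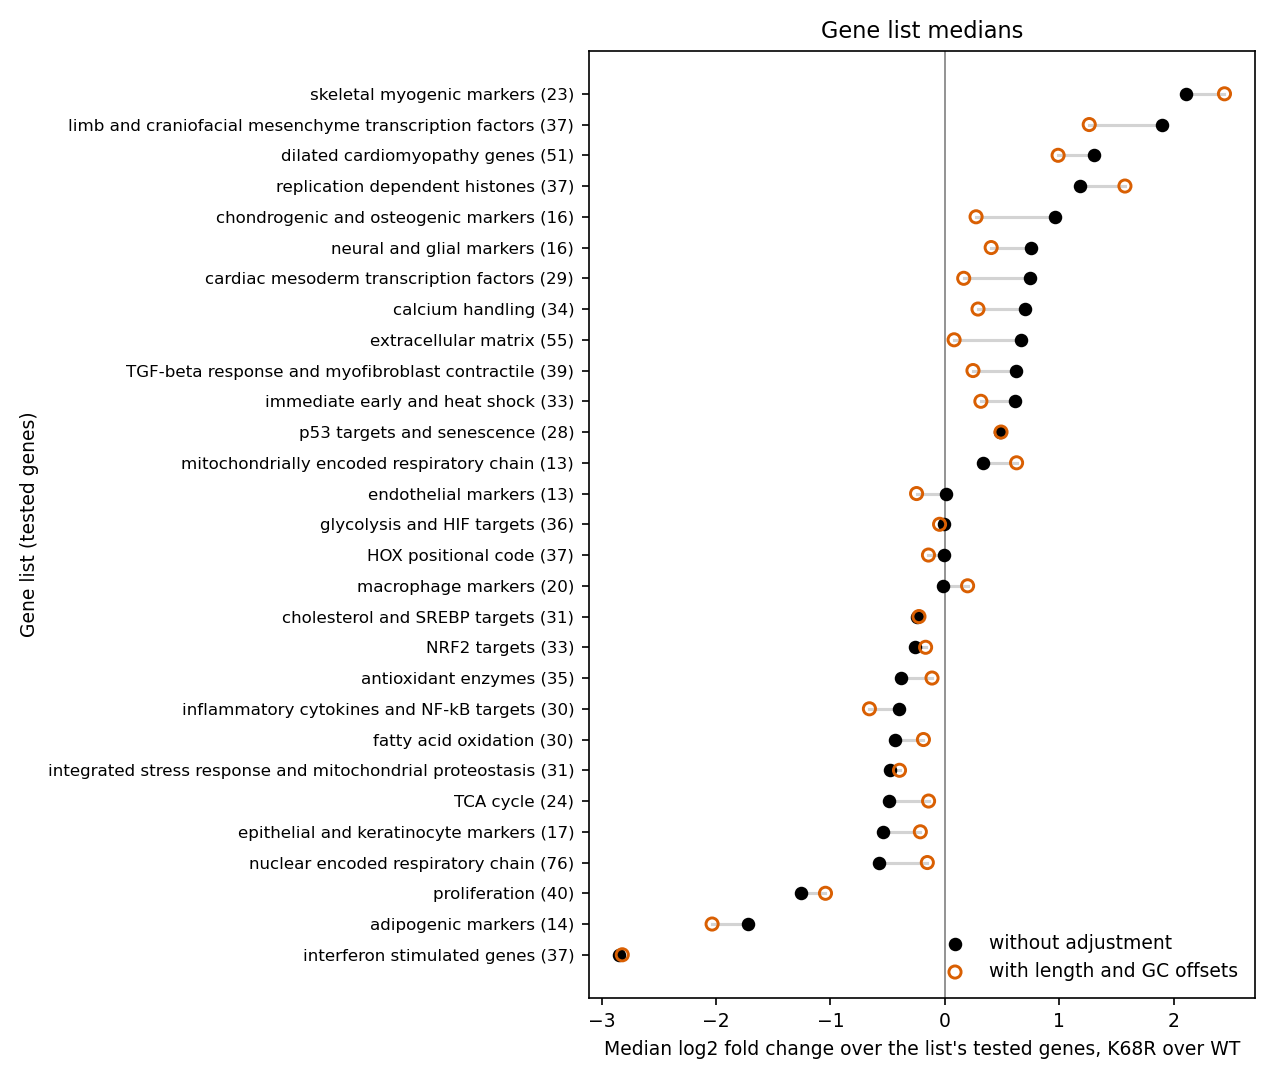
Median log2 fold change of K68R over WT (horizontal axis) of the 29 tested gene lists (vertical axis, number of tested genes in parentheses), unadjusted as filled points and with length and GC offsets as open points. Interferon stimulated genes lie at -2.85 and -2.82 and skeletal myogenic markers at 2.11 and 2.44, while extracellular matrix moves from 0.66 to 0.08.

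Genotype and any difference in culture or library preparation coincide, since no label ties libraries of both genotypes to a shared batch, and the names of the WT libraries alone carry a suffix r whose meaning is not given in the sources used here. Sample numbers in the file headers run on from the WT to the K68R libraries, which does not tell whether culture or preparation was shared. The 2.19% coefficient of variation is that of these libraries.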

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

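The alternatives with length and GC offsets and with short genes of low GC content alone were chosen after seeing the data; the others were fixed beforehand. Called genes numbered 6855 against a 1.5-fold bound (edgeR glmTreat; 4365 higher, 2490 lower) and 2735 of 3979 tested among short genes of low GC content (1358 higher, 1377 lower), where fewer genes were tested. Leaving out each library in turn gave 13403 to 13637 called genes, 6760 to 6849 higher and 6643 to 6802 lower, 18 to 19 called lists and a Sod2 log2 fold change of -0.60 to -0.54. Sod2, at -0.57, was not called against the 1.5-fold bound and kept its direction and call under the other alternatives, where it was -0.69 with upper quartile scaling and -0.14 in short genes of low GC content. Upper quartile scaling moved the median of all genes from -0.01 to -0.12 (log2) and changed the sign of 1 list median, that of endothelial markers. Genes at least 2-fold higher fell from 3704 to 1963 and at least 4-fold higher from 1683 to 618 with length and GC offsets, those at least 4-fold lower rose from 278 to 483 without a filter, and in short genes of low GC content 412 and 134 were higher and 226 and 62 lower by these bounds. No other count of called genes moved by over 1.5 times.

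Called lists fell from 19 to 10 with an estimated correlation, and fry called 28. In short genes of low GC content 8 lists were called, but only 20 of the 29 could be tested: 6 of the 19 were called again, 8 lost the call, 5 were not tested and 2 were called only there. With length and GC offsets these genes changed sign: Ogdh (-0.15), Hk1 (-0.12), Ltbp2 (-0.38), Cacnb3 (-0.48), Srebf2 (-0.065), Hoxb3 (-0.35), Jund (-0.87), Kdm5c (-0.11) and Lyz2 (0.19), and Lyz2 also among short genes of low GC content (0.15). The offsets remove most of the trend by construction, but not all of it. Genes of at least 8000 exonic bases kept a median of 0.55 (log2) at 60% GC and over. At 55% to 60% GC they kept 0.22 (log2). Over the alternatives fixed beforehand 1800 values of named genes kept direction and call, 9 lost the call, each against the 1.5-fold bound, and none reversed. With offsets Xist and Ddx3x lost theirs.

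These list tests gave the opposite direction (adjusted p): glycolysis and HIF targets with DESeq2 size factors (0.999) and fry (4.94e-05), cholesterol and SREBP targets with fry (2.37e-05) and in short genes of low GC content (0.75), macrophage markers with fry (0.421), offsets (0.0934) and in short genes (0.427), epithelial markers with fry (0.000103) and offsets (0.962), endothelial markers without WT replicate 2 (0.999; range 0.67 to 0.999), and in short genes extracellular matrix (0.0576) and cardiac transcription factors (0.76). The cause was not tested.

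The replicate number as a replicate block gave 13567 called genes, 18 lists, extracellular matrix no longer called (adjusted p = 0.0612), and Sod2 at -0.57. No label pairs the samples by number, and their deviations do not decide it. Deviations of same-numbered libraries correlated at 0.034, 0.002 and 0.065, and those of other pairs at -0.059 to 0.023. All are small, in libraries that differ little within a genotype. K68R replicate 2 correlated more with WT replicate 1 (0.023) than with its own number. Depth limits genes near 0.0728 to 0.116 CPM.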

Other observations

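The length and GC offsets, with every value and test that uses them, the collagen and sex chromosome ratios, and the tests of variance explained over genes outside every list, of the macrophage markers and of the likeness of libraries were chosen after the results were seen. The tests in classes of expression, of genomic span, of matched extracellular matrix lists, of batches and of splits of the libraries were written before their results. The reading of the matrix test was changed after its result, as given below. The test of batches could not come out otherwise, since it only counts what the labels state. Camera called none of the 3 marker lists of further cell types that follow, whereas fry, which does not compare a list with other genes, called all 3 higher: neural and glial (adjusted p = 3.05e-06), endothelial (0.00268) and epithelial (0.000103). Neural and glial markers had 11 higher, 4 lower and 1 not called of 16, with a median of 0.75 and 0.41 with offsets (log2), and were not called (camera, adjusted p = 0.0677), though upper quartile scaling called them higher (adjusted p = 0.0434). Nes, the intermediate filament nestin of progenitor cells, was 37.8-fold higher at 334 ± 1.91 against 8.87 ± 0.974 CPM (SD, n = 3), and 10.6-fold higher with offsets. Endothelial markers had 5 higher, 4 lower and 4 not called of 13 and a median of 0.01, which was -0.25 with offsets and below 0 with upper quartile scaling (camera, adjusted p = 0.872). The endothelial receptor Kdr was 4.46-fold higher and Flt1 1.60-fold lower, with 1.57 and -1.87 after adjustment (log2). Epithelial and keratinocyte markers had 6 higher, 9 lower and 2 not called of 17, with a median of -0.54 and -0.21 with offsets (camera, adjusted p = 0.69), and contained both Dsp, the desmosome protein desmoplakin, 14.8-fold higher (6.47-fold with offsets), and Krt14, 36.1-fold lower, with -5.25 (log2) after adjustment. Of 4 tested erythroid and hepatic markers, Apob was higher and Afp lower, and 2 were not called, with a median of -0.25 and 0.07 with offsets (log2). The HOX genes, which keep a record of position along the body, had 14 higher, 16 lower and 7 not called of 37. Their median was -0.01, while their mean (0.09) and the list test pointed up (camera, adjusted p = 0.873), and the median was -0.14 with offsets. Hoxb4 and Hoxb9 were 2.77-fold and 1.86-fold higher.

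Transcripts of the X and Y chromosomes were present in every library. Xist, the X-inactivation RNA of female cells, was at 175 ± 2.54 CPM in K68R and 136 ± 2.99 CPM in WT, and Ddx3y, a helicase gene of the Y chromosome, at 51.0 ± 3.28 and 76.8 ± 1.90 CPM (SD, n = 3). The ratio of Ddx3y to Xist was 0.291 ± 0.015 in K68R and 0.566 ± 0.025 in WT (SD, n = 3; exact permutation p = 0.1, the smallest possible). Of 9 tested sex linked genes 2 were higher, 6 lower and 1 not called, and the Y-linked Eif2s3y, Kdm5d and Uty had log2 fold changes of -0.52, -0.93 and -0.43. The median of the sex linked genes was -0.37, and -0.105 with offsets (log2). With offsets the log2 fold change of Xist was 0.00 and that of Ddx3y -0.27. The other Y-linked genes also stayed lower, with Eif2s3y at -0.40, Kdm5d at -1.03 and Uty at -0.68 (log2). Among 5 tested genes that differ between C57BL/6 substrains 3 were higher, 1 lower and 1 not called, with a median of 0.59 and 0.53 with offsets (log2). Cyfip2 was 9.29-fold higher (3.30-fold with offsets) and Fgfbp3 2.44-fold higher (2.94-fold with offsets). Nnt, the mitochondrial transhydrogenase disrupted in C57BL/6J, had counts in both genotypes, at 84.6 ± 0.692 and 56.1 ± 1.04 CPM (SD, n = 3). Counts over the whole gene do not resolve the exons deleted there. Of 13 tested neighbours of Sod2, 6 were higher, 5 lower and 2 not called, with a median of 0.115 and 0.315 with offsets (log2), the receptor Igf2r 3.99-fold higher (1.93-fold with offsets) and the chaperonin gene Tcp1 1.58-fold lower (1.23-fold with offsets), 32.3% of whose exonic bases are shared with other genes. The chains of type I collagen, which assemble in a fixed proportion, diverged: the ratio of Col1a1 to Col1a2 was 1.02 ± 0.011 in K68R and 0.27 ± 0.0033 in WT (SD, n = 3; exact permutation p = 0.1, the smallest possible). Length and GC offsets narrowed the divergence, with log2 fold changes of 3.89 for Col1a1 and 1.98 for Col1a2 unadjusted and 1.41 and 0.56 adjusted.

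Long transcripts rich in G and C were higher in K68R. A surface over exon length and GC content, fitted without a gene's own chromosome, explained 0.409 of the variance of log2 fold changes over 14760 genes outside every list, and at least 0.267 in each of 3 classes of expression. An effect on transcription through long genes was argued against, since the partial rank correlation was 0.06 with genomic span and 0.324 with exon length. A general rise of extracellular matrix genes beyond length and GC content was not shown and stays open, since the list median lay at percentile 76.2 of 10000 random lists matched on both, within their range. Fn1 and Col4a2 stayed higher with offsets, but they were picked for their small p and do not speak for the list. Unequal recovery of such transcripts between the libraries of the 2 genotypes, for instance through RNA integrity or amplification, is a candidate explanation, and an effect of genotype on them stays open and untested.

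Interferon stimulated genes were lower in K68R. Length and GC content were argued against as the cause, since with offsets the list median was -2.82 (bootstrap 95% interval over genes -3.33 to -2.24). A general fall of macrophage markers, which a large loss of macrophages would give, was argued against too. Their median was -0.012 (-0.245 to 0.312), with Lyz2 at 82.7 and 100.4 CPM and members moving both ways, Fcgr1 3.01-fold lower and Laptm5 3.15-fold higher. The median of a list with mixed directions does not measure the share of macrophages, so a smaller loss stays open. The labels give 0 batches that hold libraries of both genotypes, so a culture or library batch that coincides with genotype and the genotype itself cannot be told apart. Either may account for the lower level.

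Libraries of a genotype were nearly alike, with a biological coefficient of variation of 0.0219, which may reflect libraries drawn from 1 pool of cells or RNA per genotype. Each library from the cells of 1 embryo was argued against, since 6 of 6 libraries held both Xist and Ddx3y at 10 CPM or more. For the calls between genotypes, 3 against 3 libraries make 10 splits, too few for a share under 0.05. The real split called 13613 genes, which 1 of the 10 reached, and the highest of the other 9 called 0 (edgeR), with 27 to 48 genes at an unadjusted p under 0.05. Each of these 9 splits mixes the genotypes, so the genotype difference widens the spread within its groups. Few calls would follow whatever the cause of that difference.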
